A study of Mus musculus with 3 samples.

How the data were processed

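Total RNA from 3 pools of neural retina of Rp1 knockout mice was hybridised to 3 arrays of the U74Av2 type, per the labels' titles and descriptions; its control probe sets carry Affymetrix names. Each array was 1 sample of a single group. Nothing in the labels gives a batch, a scan date, a sex or a replicate number, so the pools were numbered in the order of the series. Each RNA sample is described as a pool of mice, with no statement on whether the pools shared litters or collection days.

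The authors deposited a table of linear intensity values, with 1 value per probe set and array. The software that summarised the probes is not given in the sources used here. The values were all above 0, and the mean after trimming 2% at each end was 500 units on every array (500.25, 500.27 and 500.26), which shows that the arrays had been scaled to a common level before deposit. No detection calls were used here. The table had 12489 rows, of which 1 was empty. Genes were taken from the platform annotation: 10855 probe sets had 1 gene symbol, 396 had several and 1237 were not paired with a gene. The 66 control probe sets, of which 22 had 1 gene symbol, were left out of the gene table. Of the 10833 probe sets used, 10817 had a gene identifier that matched the reference gene table (assembly GRCm38.p6), and 0 symbols needed an update. No coordinates are given because the sources used here name no genome build for the array.

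Each array was scaled to the mean of the 3 trimmed means, which moved the values by a negligible factor, and values under 20 units (9.05%, 10.6% and 11.4% of probe sets in pools 1, 2 and 3) were raised to 20 before taking log2. A gene with several probe sets (2073 genes) was represented by the probe set with the highest mean. For some named genes, such as Pdc, Apoe, Fos, Bcl2l1, Cry1 and Col1a2, another probe set lay below background. The background level of an array was the 90th percentile of 43 measured genes of a list of 49 genes of other tissues. Gene lists for retinal cell types, other eye tissues and cellular programmes were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The rule named up to 3 brightest and up to 2 most variable members above background of each list, all sex-linked genes, and the 12 widest genes with an adjusted p under 0.05 and above background on at least 1 array. Some named genes stand in several of these classes.

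Between-pool spread was tested with limma 3.58.1 in R 4.3.3. An intercept-only model was fitted to the 3157 genes whose mean exceeded the mean background level. Each gene's variance, with 2 residual degrees of freedom, was compared by an F test with a prior variance fitted robustly as a function of intensity, with 17.5 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg. The test was checked on simulated data with the same 3157 genes. With 200 genes given a wider SD, it recovered 0% of them at 3 times the prior SD, 54.5% at 5 times and 70% at 8 times, with 0, 1 and 0 false calls, and 0 false calls when no gene was widened. The prior degrees of freedom it found in these simulations ran from 7.26 to 27.4 where 17.5 had been set, so the strictness of the test is itself uncertain with 3 arrays. Lists were set against 10000 random lists of as many genes, unmatched for intensity and matched within 20 intensity bins for spread and shift, with 97.5% and 2.5% as bounds (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). These percentiles describe the 3 arrays and are not p-values, because genes are not replicates.

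The alternatives were values as deposited, quantile normalization, a floor of 100 units, log2(value + 16) with no floor, the mean of all probe sets of a gene, leaving out probe sets with an ambiguous suffix, background at the 75th percentile or at the highest of the 15 control probe sets for the bacterial genes dap, lys, phe, thr and trpn (a selection fixed before the data were examined, which leaves out the bright bio and cre controls), a non-robust prior, no filter on dim genes, unmatched random lists and leaving out each pool in turn. Removing the lens genes before the fit was added after the data were seen. The planned value for Rp1 was not computed because no probe set was paired with it.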

Results

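Transcript levels were measured in the neural retina of mice that lack Rp1, a photoreceptor gene whose product is associated with the microtubules of the connecting cilium and outer segment axoneme. Retinas were taken on postnatal day 18, in the early afternoon, from mice on a mixed genetic background. The series holds 3 Affymetrix U74Av2 arrays, each hybridised with RNA from a pool of neural retinas of 3 to 4 mice, and all 3 belong to the knockout group. No wild-type or other control array was analysed here. The data therefore give the intensity of each transcript in Rp1-deficient retina and its spread between pools, and no change caused by the mutation can be read from them. The pools are called pool 1, pool 2 and pool 3. The numbers only name them. The labels do not say that the pools came from separate litters or collection days, so a p-value measures only the spread between these samples, which may be technical.

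Each array gave an intensity for 12488 probe sets, and the 10833 probe sets paired with a single gene represented 8251 genes. Median intensities were 238.1, 220.25 and 225.1 units in pools 1, 2 and 3. The number of arrays, 3, limits the precision of every mean. No probe set was paired with Rp1 or with its relative Rp1l1, so the targeted gene itself could not be checked in any array. Genes of other tissues, such as liver, pancreas and testis, served as the background, and the level that 90% of them stayed under was 460 units in pool 1, 495 in pool 2 and 521 in pool 3. By this measure 2716 genes, 32.9% of those represented, were above background on all 3 arrays. The 15 control probe sets for the bacterial genes dap, lys, phe, thr and trpn reached at most 105.7, 95.3 and 93.2 units, and 5598 genes exceeded these levels on all arrays. Other bacterial and phage controls were bright, such as a bioB probe set at 2885, 4371 and 2306 units and a cre probe set at 56690, 66586 and 43506, and were not used as background.

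The first question was which retinal cell types and programmes gave strong signals in the knockout retina on day 18. Rod phototransduction transcripts were bright, and 10 of the 12 measured members were above background on all arrays. Gnat1, the rod transducin alpha subunit, had 42312 ± 6319 units (SD, n = 3). Sag, the rod arrestin, had 34630 ± 5616 units, and Pdc, phosducin, had 28680 ± 2780 units. Gnb1, the transducin beta subunit, had the widest spread of the list at 14494 ± 5084 units, which did not pass the test for excess spread (limma, adjusted p = 0.467). Its values were 13942, 9709 and 19831 units in pools 1, 2 and 3. The other Gnb1 probe sets, not tested singly, were also highest in pool 3, with 2413, 2611 and 8529 and with 8131, 7595 and 14400 units. The median of the list, 13.45 on the log2 scale, lay above all 10000 random lists of as many genes, whose typical median was 8.32. A bright list is a statement about its probe sets as a group, because single probe sets differ in affinity and cannot be ranked against each other.

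Other photoreceptor transcripts were bright too. Of the outer segment and cilium list, 7 of 9 measured members were above background. Tulp1, needed for protein transport in photoreceptors, had 13418 ± 1724 units. Prom1, a protein of nascent outer segment discs, had 10938 ± 214 units, and Abca4, the retinoid flippase of the disc rim, had 8014 ± 840 units. Ift88, a component of intraflagellar transport, had 2628 ± 372 units. Among photoreceptor transcription factors, 5 of 7 were above background, with Crx at 6465 ± 464, Mef2d at 7660 ± 348, Neurod1 at 5053 ± 920 and Nrl at 740 ± 113 units. Cone transcripts were above background for 4 of 8 members. The short-wavelength opsin Opn1sw had 3590 ± 886 units, the middle-wavelength opsin Opn1mw 2057 ± 330, the cone transducin subunit Gnat2 2827 ± 369 and Gnb3 3488 ± 324. The outer segment and transcription factor lists exceeded 100% and 99.2% of random lists. The cone list, at 95.8%, did not reach the preset bound.

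Transcripts of inner retinal cell classes were also above background. Müller glia gave 8 of 9 measured members above background, among them Apoe at 8210 ± 2193, clusterin (Clu) at 5543 ± 1015 and Dkk3 at 4709 ± 746 units. Of the amacrine and horizontal cell list 7 of 16 members were above background. Calretinin (Calb2) had 6183 ± 310 units, the GABA-synthesising enzyme Gad1 had 4766 ± 425, the vesicular GABA transporter Slc32a1 had 3164 ± 721 and Pax6 had 2170 ± 416. Ganglion cell transcripts were above background for 6 of 9 members, with Thy1 at 2326 ± 830, neurofilament light chain (Nefl) at 1503 ± 250, Stmn2 at 1450 ± 138 and Sncg at 1220 ± 363 units. Only 4 bipolar cell genes were measured. Pcp2 had 1984 ± 682 units, Isl1 1010 ± 206 and protein kinase C alpha (Prkca) 523 ± 55. Synaptic genes included Snap25 at 12538 ± 1212, Vamp2 at 6321 ± 1432, Syt1 at 5290 ± 760, Syp at 1679 ± 395 and Pclo at 905 ± 276 units. The Müller, ganglion cell and synaptic lists were brighter than 100%, 99.3% and 99.8% of random lists, while the amacrine and bipolar lists, at 89.8% and 86.8%, were not beyond the bound. With the mean of all probe sets of a gene, the ganglion cell list stood at 93.5% and the cone list at 98.5%.

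Genes of energy metabolism and translation were likewise bright. All 14 measured glycolytic genes were above background, including Pkm at 19468 ± 1700, Aldoa at 17165 ± 3004, Ldha at 14399 ± 1273, Pfkl at 4494 ± 963 and hexokinase 1 (Hk1) at 3880 ± 895 units. Oxidative phosphorylation had 19 of 25 members above background, such as Atp5a1 at 7657 ± 760, Cox6a1 at 6989 ± 1258, Cyc1 at 6520 ± 652, Atp5o at 1989 ± 615 and Ndufa2 at 1582 ± 332 units. Ribosomal proteins had 15 of 19, with Rpl41 at 28052 ± 4704, Rps24 at 20889 ± 3436, Rplp0 at 9302 ± 1405, Rps7 at 7441 ± 1599 and Rps19 at 1611 ± 370 units. Each of these lists exceeded 100% of random lists.

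Genes of gliosis, cell death, the cell cycle and immune cells were near or below background for most members. Of the gliosis and photoreceptor stress list 5 of 13 were above background. Metallothioneins Mt2 and Mt1 had 1618 ± 491 and 1440 ± 181 units, and Stat3, a transcription factor of cytokine signalling, had 1123 ± 238. Of the apoptosis list 4 of 14 were above background, with Bcl2l1 at 1346 ± 281, Casp2 at 1037 ± 95 and Aifm1 at 968 ± 107 units. The other Bcl2l1 probe set had a mean of 18.5 units. Pcna, at 870 ± 114 units, Ccna2, at 702 ± 181, and Plk1, at 638 ± 78, were the 3 of 15 cell cycle genes above background. None of 14 microglia and macrophage genes was above background on all arrays. Their brightest members were C1qc at 480 ± 46, C1qb at 455 ± 137 and Ctss at 453 ± 32 units. Of 11 vascular genes only endoglin (Eng), at 843 ± 165 units, was above background on all arrays, while Kdr had 510.5 ± 169 and Cldn5 487 ± 36 units. Immediate early genes were above background for 3 of 12 members, namely Btg2 at 2365 ± 294, Dusp1 at 951 ± 230 and Fos at 654 ± 175 units. Clock genes were above background for 6 of 14 members, with Nr1d2 at 1930 ± 186, Tef at 1720 ± 658 and Cry1 at 1439 ± 280 units. The other Cry1 probe sets had means of 16.3 and 17.6 units, so its level is uncertain. None of these lists stood outside the range of random lists in the main setting. The microglia list was at percentile 1.15 with the mean of all probe sets of a gene, and without probe sets of ambiguous suffix the microglia list was at 2.2 and the cell cycle list at 0.46, all below the bound. The background list itself was dimmer than all 10000 of them and still held 3 bright probe sets, for Tff1 at 1465 ± 113, Tnp1 at 805 ± 81 and Lor at 714 ± 113 units.

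**Figure D1:**
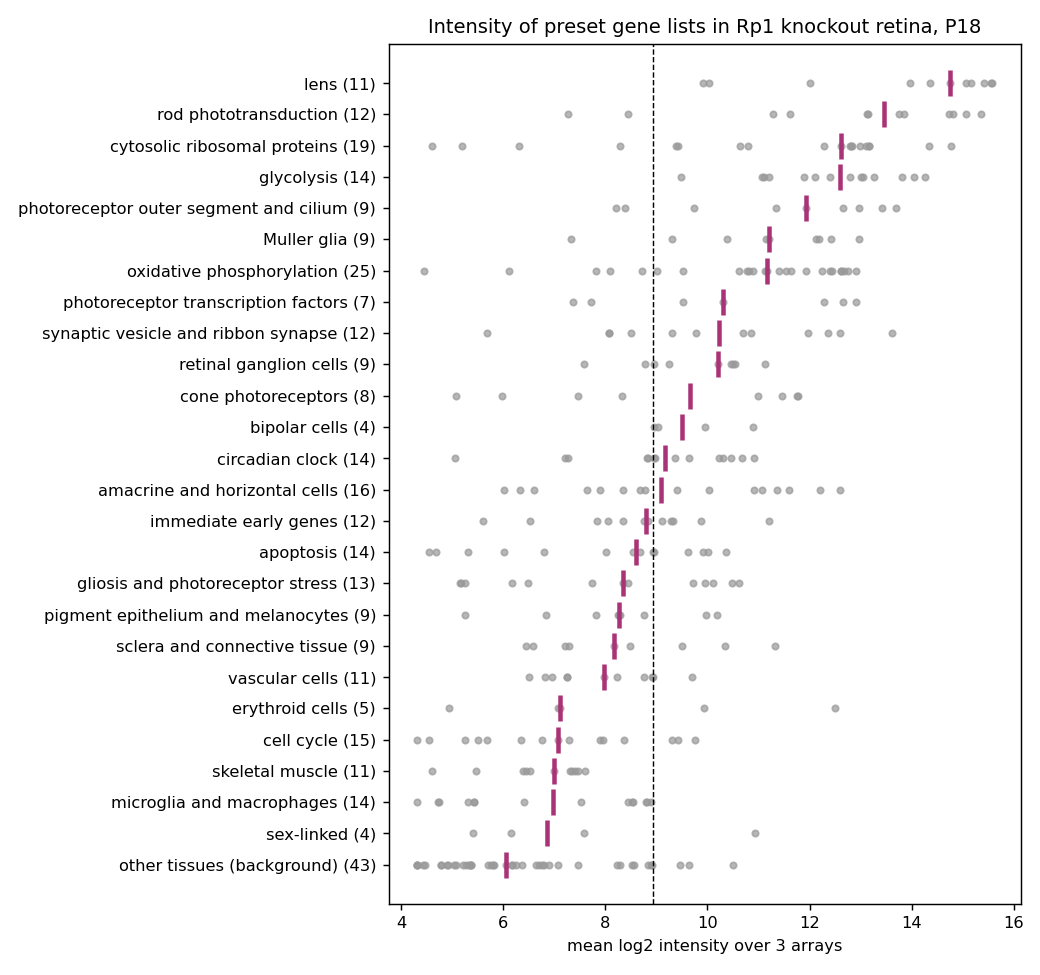
Intensity of 26 gene lists fixed before the data were examined. Each grey point is a gene's mean log2 intensity over the 3 arrays, each purple bar is the median of the list, numbers in brackets are the genes measured, and the dashed line is the mean background level. The lens and rod lists have the highest medians, and the list of other tissues has the lowest.

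The second question was which transcripts differed between pools of the same genotype. The most prominent were those of the lens. All 11 measured genes of the lens list were highest in pool 2, intermediate in pool 3 and lowest in pool 1. Gamma-crystallin C (Crygc) had 9424 units in pool 1, 59897 in pool 2 and 36820 in pool 3, a 6.36-fold range. Mip, the water channel of lens fibre cells, had 259.6, 2500.4 and 1816 units. Its value in pool 1 was below background, so that its range was at least 5.44-fold. Beta-crystallin B2 (Crybb2) ranged 5.31-fold, Crygb 4.38-fold, Crygs 4.25-fold and Crygd 3.20-fold. The other Crybb2 probe set, far dimmer, did not share this order, with 870.1, 873.1 and 1248.6 units. The other probe sets of Crygb and Crygd, also far dimmer, did share it, with 576.6, 2585 and 1464.4 units and with 242.7, 685.3 and 366.3 units. Cryaa and Cryge, which had means of 51543 ± 21833 and 50328 ± 17748 units (SD, n = 3), ranged 2.37-fold and 2.06-fold and did not pass the test over all genes. Another Cryge probe set, nearly as bright but not tested singly, had the same order and a wider range, with 21210.5, 67533.5 and 41726.7 units. Of the dim Cryge probe sets, the one with 51.9, 322.4 and 66.3 units shared the order. The one with 255, 246.8 and 267.6 units did not. Crygd in pool 2 and Cryge in pool 3 had the highest values of their arrays, and whether such bright probe sets were near saturation was not tested.

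Of 3157 genes tested, 18 had a between-pool variance above that of genes of like intensity (limma one-group fit, robust prior variance, Benjamini-Hochberg adjusted p under 0.05), and 189 had an unadjusted p under 0.05. The lens list held 8 of the 18 calls, against a total of 11 lens genes tested. All 11 passed when adjusted over the list alone. The same adjustment called 2 erythroid genes, 1 pigment gene and 1 synaptic gene that were not called over all genes. Over all 3157 tested genes, the lowest adjusted p-values within the lens list were 0.000172 for Mip, 0.000177 for Crygc and 0.000463 for Crybb2 (limma). The other lens calls were Crygb, Crygs, Crygd, Cryba1 and the lens filament gene Bfsp1, of which Cryba1 and Bfsp1 were named only after their values were seen. Crygd and Cryge were read by probe sets that can match several of the near-identical gamma-crystallin genes, so their values are uncertain as single genes. Without pool 1 the test called 4 genes, of which Prp2 and Rnf10 were among the 18, and without pool 3 it called 0 genes (limma, 134 at an unadjusted p under 0.05). Without pool 2 it called 13, of which 12 were among the 18. A prior fitted without the robust step gave 10 calls, all among the 18, and background at the highest of the 15 dim bacterial controls gave 11, of which 8 were among the 18. Quantile normalization gave 12 calls, all among the 18.

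Of the 10 calls outside the lens list, 5 shared its pool order. Fabp5, an epidermal fatty acid binding protein, had 652 units in pool 1, 5650 in pool 2 and 2509 in pool 3 (adjusted p = 0.00022). Cd24a, a cell surface glycoprotein, had 1481, 8764 and 6652 units (adjusted p = 0.00022). Hmox1, the inducible haem oxygenase, had 1289, 5782 and 3862 units (adjusted p = 0.00323), and Tcp11 had 171.1, 1214.6 and 684 units (adjusted p = 0.00166), of which the value in pool 1 was below background. Prph2, the disc rim protein peripherin of photoreceptor outer segments, had 1735, 7109 and 4769 units (adjusted p = 0.00439) and a 4.10-fold range. Prph2 is read by a single probe set. The remaining calls had other orders. Mt3, a metallothionein of neural tissue, had 3188 units in pool 1 against 742 and 949 in pools 2 and 3 (adjusted p = 0.00759). Sncb, beta-synuclein, had 5861 units in pool 1 against 2545 and 1881 (adjusted p = 0.0486). Rnf10 was low in pool 2 only, at 1699 units against 5578 in pool 1 and 4970 in pool 3 (adjusted p = 0.0149). Prp2 had 891, 1340 and 318 units (adjusted p = 0.0267), and its other probe set had 711.4, 315.5 and 324.4 units, a different order. The value of Prp2 in pool 3 was below background. Sncb and Rnf10 were named after their values were seen. With the lens genes left out of the fit, a choice made after the data were seen, 9 of these 10 genes were called, and Sncb was not (limma, adjusted p = 0.067). Each of these adjusted p-values is from the limma test of spread. When all genes were tested, including those below background, no gene was called (165 at an unadjusted p under 0.05).

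Transcripts of sex chromosomes differed as well. Xist, the RNA of the inactive X chromosome, had 731.9 units in pool 1, 2203.8 in pool 2 and 4748 in pool 3, a 6.49-fold range (limma, adjusted p = 0.00101). The Y-linked gene Eif2s3y had 390.6, 519.6 and 34.1 units, above background in pool 2 only, on a probe set that can match related genes. Kdm5d had 74.5, 52.6 and 15 units and Uty had 82.7, 78.8 and 55.6 units, all below background. The mean of each of these 3 Y-linked genes lay below the level required for the test, so no adjusted p is given for them.

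**Figure D2:**
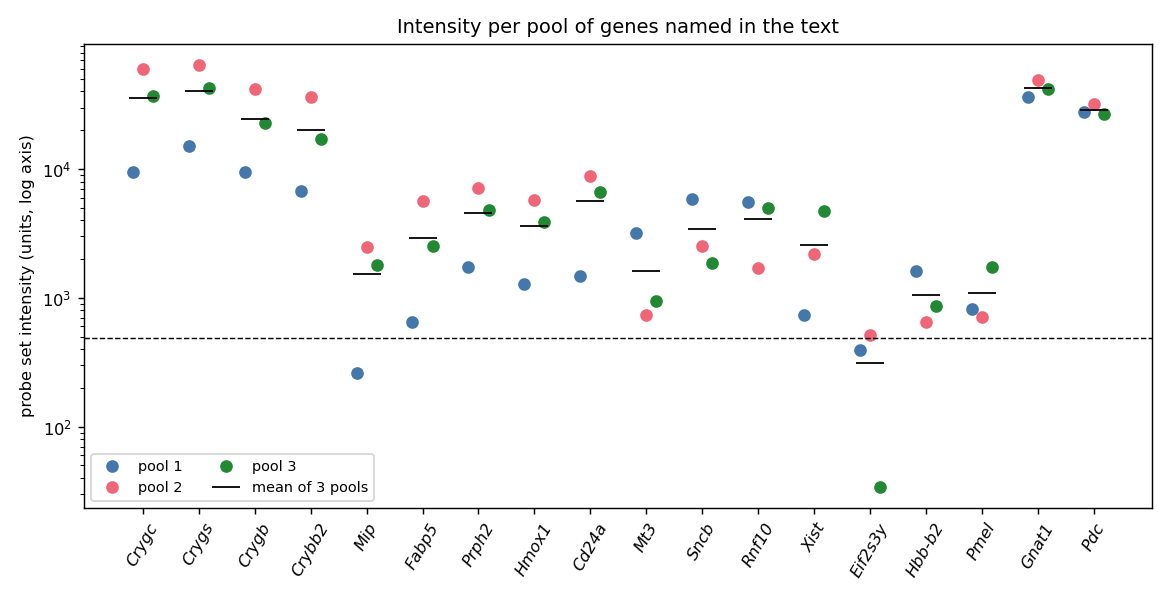
Intensity of named genes in each pool, on a log axis. Points are single arrays, black bars the means of the 3 pools and the dashed line the mean background level. Crystallin genes, Mip, Fabp5, Prph2, Hmox1 and Cd24a are lowest in pool 1, and Xist and Eif2s3y go opposite ways in pool 3, whereas Gnat1 and Pdc lie close together.

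The shift of whole lists was then compared with 10000 random lists of like intensity. The lens list differed from the other pools by -1.25 log2 units in pool 1 and 1.34 in pool 2, both beyond all random lists, and by 0.19 in pool 3 (percentile 97.8). The shift in pool 2 was 0.83 after quantile normalization and 0.64 without pool 1, and the shift in pool 3 was -0.64 without pool 1 and 0.96 without pool 2. The shift in pool 3 was also within the random range with the mean of all probe sets of a gene (percentile 97.4), without probe sets of ambiguous suffix (92.9) and against random lists not matched for intensity (91.8). Pigment epithelium and melanocyte genes differed by -0.73 in pool 2 (percentile 0.05) and 0.55 in pool 3 (percentile 99.8). Only 2 of the 9 measured members, Pmel and Dct, were above background on all arrays, and the median in pool 3 was that of Rdh5, which was below it in every pool. Pmel, a melanosome matrix protein, had 817.5, 715.2 and 1723.5 units in pools 1, 2 and 3, and Dct, an enzyme of melanin synthesis, had 1213, 854 and 1553 units. Both missed the threshold of the limma test over all genes (adjusted p = 0.411 and 0.89). Adjusted over the 2 tested genes of the list alone, Pmel passed and Dct did not. The shift in pool 3 was -0.11 without pool 2 and 0.99 without pool 1. Transthyretin (Ttr), at 434 ± 48 units, was not above background. Erythroid genes differed by 0.73 in pool 1 (percentile 98.2) and -0.64 in pool 2 (percentile 1.62). Only 2 of the 5 measured members, both globins, were above background on all arrays, and the median in pool 2 was that of Slc4a1, which was below it in every pool. The alpha-globin Hba-a1 had 8125, 4768 and 5050 units, Hbb-b2 had 1627, 652 and 871 units, and the haem synthesis gene Alas2 had 217.1, 77.2 and 158.1 units, below background. Neither globin passed the limma test over all genes (adjusted p = 0.761 and 0.426). Both passed when adjusted over the 2 tested genes of the list alone. The erythroid shift in pool 1 was 0.47 without pool 2 and that in pool 2 was -0.40 without pool 1, both within the random range.

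Ribosomal protein genes differed by -0.32 in pool 3 (percentile 0.08), and by -0.25 without pool 2, just inside the random range. The sex-linked list, of whose 4 measured members 3 are Y-linked, differed by -1.09 there (percentile 0.42). Its shift was -0.54 without probe sets of ambiguous suffix and 0 with a floor of 100 units, both within the random range. Ganglion cell genes differed by 0.32 in pool 1 (percentile 97.9). This shift was -0.02 without pool 3, 0.31 without pool 2 and 0.12 without probe sets of ambiguous suffix, each within the random range, and it was at percentile 91.7 among random lists not matched for intensity. Thy1 had 3208, 2209 and 1561 units and missed the threshold (limma, adjusted p = 0.691). In total 10 of the 78 list and pool values lay outside the central range, where chance gives 3.9 for genes drawn at random. Genes of a list can vary together, and the shifts of a list in the 3 pools depend on each other, so this is no test. Without pool 2, where the values of the remaining pools mirror each other, only the lens list lay outside the central range. Rod phototransduction differed by -0.07, 0.12 and -0.05 in pools 1, 2 and 3, within the random range. Skeletal muscle and connective tissue lists, which can mark extraocular tissue, were within the range too. No muscle gene was above background on all arrays, the brightest being Mylpf at 220 ± 132 units. Sparc, Col1a2 and Fn1 had 2576 ± 351, 1310 ± 227 and 730 ± 55 units. The other Col1a2 probe set had a mean of 39.3 units. The ratio of 3' to 5' probe sets of beta-actin, a measure of RNA integrity, was 1.85 in pool 1, 1.56 in pool 2 and 1.39 in pool 3, so that pool 1, the lowest for lens genes and the highest for the globins Hba-a1 and Hbb-b2, also had the highest ratio.

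**Figure D3:**
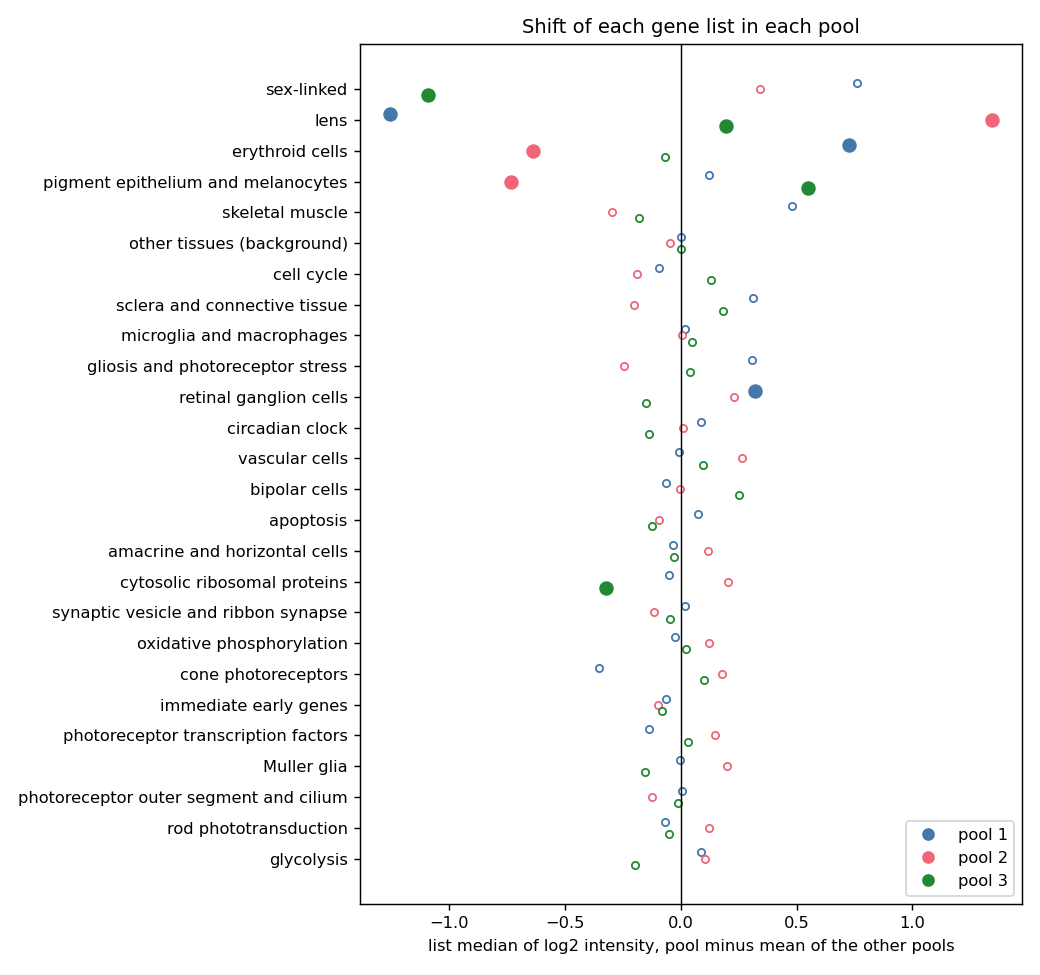
Median shift of each gene list in each pool, as log2 intensity of the pool minus the mean of the other pools. Large filled points are outside the central range of 10000 random lists of like intensity, small open points are inside it. The lens list is displaced to -1.25 in pool 1 and 1.34 in pool 2, while the rod list lies between -0.07 and 0.12.

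The spread of most genes was small next to these differences. The median between-pool SD of the 2716 genes above background was 0.204 on the log2 scale, a factor of 1.15. Across genes above background, Pearson's r between arrays was 0.935 for pools 1 and 2, 0.922 for pools 1 and 3 and 0.951 for pools 2 and 3, where genes are not independent replicates. The number of genes that differed more than 2-fold was 37, 52 and 16 for these pairs. Of the 26 lists, 3 had a wider spread than random lists of like intensity, where chance gives 0.65 for genes drawn at random. They were lens (percentile 100), pigment epithelium and melanocytes (99.7) and sex-linked genes (99.6). The pigment list was within the range without pool 2 (50.5) or pool 3 (96.2), and the sex-linked list without pool 3 (40.4) or without probe sets of ambiguous suffix (88.5).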

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

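None of these values was chosen for a planned test, and they stand here because they lie outside the genes used in the report. Of the 1589 probe sets not paired with exactly 1 gene, array controls not counted, 331 (20.8%) were above background on all 3 arrays, so part of the retinal signal on this array was not analysed here. Among them, a probe set paired with 4 beta-globin genes had 12290 units in pool 1, 6808 in pool 2 and 7511 in pool 3 (mean 8870 ± 2983, SD, n = 3). Its highest pool was 1.81 times its lowest, and pool 1 was also the highest for Hba-a1 and Hbb-b2. A group of 3 arrays was not tested for single outlying samples, and a single group allows no contrast between groups.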

How the results depend on the processing

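Leaving the lens genes out of the fit was the only alternative setting chosen after the data were seen. Genes above background numbered 4661 with the 75th percentile and 5598 with the dim bacterial controls, which were lower levels on these arrays. Bright lists numbered 10 in every alternative run, and dim lists 3 with the mean of all probe sets and 4 without suffixed probe sets (cause not tested). Besides the list of other tissues, these were microglia and skeletal muscle (percentiles 1.15 and 1.12 with the mean) and, without suffixed probe sets, also the cell cycle. Genes with excess spread numbered 0 to 13 when a pool was left out, 11 with the dim bacterial controls, 10 with the non-robust prior, 0 with no filter (limma, 165 at an unadjusted p under 0.05) and 9 without the lens genes. Of the 18 genes, 12 were called after quantile normalization, 13 with the mean of all probe sets and 13 with the 75th percentile, where 18 genes were called in all, and 14 without suffixed probe sets, where 20 were called. Without suffixed probe sets the test has no value for genes read only by one, such as Bfsp1 and Tcp11. Leaving out a pool leaves fewer samples to estimate a variance, and the cause of the other changes was not tested. The prior degrees of freedom were 17.5 in the main setting, 5.54 without pool 3 and 3.61 with no filter. Without pool 1 or without pool 2 they were infinite. The strictness of the test therefore differed between these settings, and their numbers of calls are not directly comparable. Shifts outside the bounds numbered 2 to 12 of 52 with a pool left out, where chance gives 2.6 for genes drawn at random. The values of the remaining pools mirror each other there, so these are not comparable with 10 of 78. Shifts that reversed, each only with a pool left out, ran from -0.019 to 0.31 for ganglion cells in pool 1, -0.11 to 0.99 for the pigment list in pool 3 and -0.64 to 0.96 for the lens in pool 3. The median SD ran from 0.154 to 0.241. Of 234 brightness percentiles 227 kept their side of the bounds, as did 248 of 260 spread percentiles. Of 90 values of the 10 shifts outside the bounds in the main setting, 75 kept their sign and stayed outside. Values as deposited tested nothing, because the arrays were already scaled. The alternatives for the level of Rp1 were not run, since no probe set was paired with it. No paired analysis was possible because there is 1 group. Genes near background have values that the floor and the background choice can move.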

Other observations

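Several bright transcripts lay outside the gene lists and were chosen after their values were seen. Unc119, a photoreceptor protein that binds lipid-modified cargo such as transducin, had 18265, 16692 and 14651 units in pools 1, 2 and 3, a mean of 16536 ± 1812 (SD, n = 3). Reep6, an endoplasmic reticulum protein of rods, had 11294 ± 1735 units, and Slc6a6, the taurine transporter, had 10512 ± 973. The chromatin protein Hmgn1 had 30207 ± 1934 units, the translation factor Eef1a1 26611 ± 2751, brain creatine kinase (Ckb) 15886 ± 1792, the prion protein gene Prnp 13363 ± 2255 and carbonic anhydrase 2 (Car2) 9378 ± 1070. None of these 8 passed the test of spread between pools (limma, adjusted p of 0.993 for Unc119, Reep6, Eef1a1, Ckb, Prnp and Car2).

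Of the tests below, only that of lens genes outside the first list was fixed before its result was seen, without its condition on background. The others were chosen afterwards.

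Lens transcripts differed between the pools, with a median pool 2 minus pool 1 difference of 1.814 on the log2 scale. Random lists of like intensity all lay below it, so such lists did not share the difference. The lens list had been picked out by such a comparison on scaled arrays, so this is no separate test of a whole-array intensity difference. Its shift in pool 2 was smaller after quantile normalization, as given above. That normalization gives every array the same highest values, which lens genes held in pools 2 and 3. The smaller shift therefore does not decide either. Crystallin transcription in retinal cells alone would leave the non-crystallin members Mip and Bfsp1 without such a difference. Their median difference was at least 2.128, with the value of Mip in pool 1 raised to the background. The values of these genes argue against that explanation, but both were already calls of the spread test when they were chosen for it. Lens tissue carried into the pools in different amounts is a candidate explanation that stays open: of 16 further lens genes, 8 were measured, and their median difference was 0.764, above 99.6% of random lists. Only Caprin2 and Cdkn1c of these 8 were above background on all arrays, so the test does not decide, and neither these nor any other of the 8 but Gja3 had the pool order of the first list, since Caprin2 was highest in pool 3 and all the rest were lowest there.

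Xist and Y-linked transcripts differed between the pools. For Xist, the pool 3 minus pool 1 difference was 2.698 on the log2 scale, where the highest of 412 other genes of like intensity had 1.944. Xist had been picked out by its spread against genes of like intensity, so this is no separate test of a whole-array intensity difference. Different shares of males and females in the pools is a candidate explanation that stays open: 3 of 3 measured Y-linked genes were lowest in pool 3, where Xist was highest, which chance gives in 3.70% of cases if the genes were independent. None of the 3 was above background on all arrays, and Eif2s3y only in pool 2, so their ranks do not decide. A Y-linked gene absent from a pool would fail that condition too, so the condition could not have favoured this explanation. Eif2s3y was above the highest of the 15 dim bacterial controls in pools 1 and 2 and below it in pool 3. Kdm5d and Uty were below that level in every pool. The labels state no sex.

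Prph2 differed between the pools, with -1.746 on the log2 scale for pool 1 minus the mean of the others. Fewer rod cells in pool 1 is argued against by the rod list, whose median for the same difference was -0.0694. Its SE of 0.0503 is across 12 genes, which are not replicates, so it does not measure error in the rod share of a pool. A variant or isoform under the probes cannot be told apart from a change in level, because Prph2 has 1 probe set. Prph2 RNA from lens tissue also stays open: its pool order was that of the lens list (1 where it matches), but it was picked out with that order in view, and 5 of the 10 calls outside the lens list had it, so the match decides nothing. No biological difference named by the design was tested, because it has a single group.

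Across all tested genes the pool order of the lens list was held by 490 of 3157 (15.5%), and among genes with an unadjusted p under 0.05 outside that list by 25 of 178. Pool 1 lay farthest from the middle value in 14 of the 18 calls, and in 8 of the 10 outside the lens list. Across all 3157 tested genes it did so in 1189.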
